A study of Arabidopsis thaliana with 2 samples.

How the data were processed

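RNA-seq was made from leaves of Arabidopsis thaliana (ecotype Columbia) plants aged 2 weeks and grown under a 16-h photoperiod at 23 °C. Per the labels, 1 library came from wild type plants and 1 from plants homozygous for Atclb1-1, a T-DNA insertion allele of AtCLB described as loss of function. Groups were taken from the genotype labels. Total RNA was extracted with a column kit, and libraries were built with the NEBNext Ultra Directional kit and sequenced on an Illumina Genome Analyzer, per the labels' protocols. How mRNA was selected, the read length, the time of day of harvest and the number of plants per library are not given in the sources used here.

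The values are FPKM, fragments scaled by transcript length and by the mapped total of the library, as deposited by the authors and named so per the file headers, with 1 column per library and 33557 loci. Per the submitters' processing notes, TopHat 1.3.2 and Cuffdiff were used with the TAIR10 build. Their parameters, the annotation release and any filters are not given in the sources used here. FPKM divides by transcript length and by the library's total, so a few abundant loci can shift all other values, and very short transcripts reach high FPKM from single reads. The kit marks strand, but whether the authors' quantification used it is not given in the sources used here. Values of overlapping or antisense genes are therefore uncertain, and 28 of the 151 distinct named loci overlap another annotated gene. Values are also uncertain for near-identical copies among which reads could be divided, namely the LHCB1 genes, RBCS1B, RBCS2B and RBCS3B, PDF1.2A and PDF1.2C, AOC1 and AOC2, the SAUR genes, and KIN1 and KIN2.

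Read counts and the authors' test values were not analysed here, so the planned count of the authors' own calls was not made. The relative depth was read from the steps of low values. Among 2434 loci above 0 and below 1 FPKM in both libraries, the ratio of mutant to wild type values piled up at 0.826, with 268 loci within 0.01 on the log2 scale against a median of 5 loci per window of that width. Further pile-ups lay 1 doubling above (140 loci) and below (89 loci). On this reading the library labelled mutant was 1.21 times as deep. The most frequent product of FPKM and transcript length, taken as 1 read on a transcript of 1 kb, lay between 0.065 and 0.07 FPKM in wild type and between 0.055 and 0.06 FPKM in the library labelled mutant. These coarser bounds put the depth ratio between 1.08 and 1.27 and imply roughly 14300000 to 15400000 mapped fragments in wild type and 16700000 to 18200000 in the library labelled mutant. The estimate rests on TAIR10.1 transcript lengths in place of the lengths the authors used. Reads per gene were not recovered, so no counting interval is given for a gene's value.

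Differences were computed as log2((mutant FPKM + 1)/(wild type FPKM + 1)) with a pseudocount of 1, which understates the difference of low genes. Loci at 1 FPKM or more in at least 1 library were kept, and a locus was counted as higher or lower at a difference of at least 2-fold on that scale. Folds printed for single genes are plain ratios of the FPKM values. With 1 library per genotype no test between genotypes was possible, and no p-value was computed. Gene lists for pathways, stress responses, cell types and reference genes were each summarised by the median difference of the members that passed the filter. Each median was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean log2 expression. Lists with fewer than 3 measured members were not placed. The percentile is a description of these libraries.

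The lists, the filter, the thresholds and the rule for naming genes were set before the data were examined. The rule named AtCLB; the 12 loci with the highest and the 12 with the lowest difference among loci at 5 FPKM or more in a library; up to 4 measured members with the largest absolute difference in each list; and the reference genes. Other list members named in the text, and all members of annotated families, were chosen after their values were seen.

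Alternatives were pseudocounts of 0.1 and 5; mutant values rescaled to set the median log2 ratio of 11724 loci at 5 FPKM or more in both libraries to 0; both libraries rescaled to the same total of nuclear loci; no filter; a filter at 5 FPKM; a 4-fold threshold; and list means in place of medians. A correction for transcript length and GC content, and a restriction to protein-coding loci with transcripts of 500 nt or more, were added after the data had been seen. The correction subtracted medians in 20 bins of transcript length and 10 bins of GC content within each. Names, coordinates, transcript lengths and GC content came from the TAIR10.1 RefSeq annotation. Of the 33557 identifiers 32810 matched it, and 99.1% of the 18171 loci that passed the filter had a transcript length. Plastid and mitochondrial identifiers did not match and carry no coordinates here.

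The steps were tested on simulated data made from the wild type values of 16952 genes, with 200 genes altered 4-fold and noise of 0.3 (SD, log2). All 200 (100%) passed the 2-fold threshold, and 0.0358% of the other genes did. Both rates follow from the fold and noise chosen, and they are not error rates of the real libraries, which have no replicates. A planted list of 15 genes reached the percentile of 100, and 4.5% of 200 unaltered lists lay outside the middle 95% of random lists. The place of the planted list likewise follows from the fold and noise chosen. The 4.5% does not carry over to the real lists, whose members need not vary independently. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.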

Results

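Leaf transcriptomes of wild type Arabidopsis and of the Atclb1-1 mutant, a line with a T-DNA insertion in AtCLB, were compared with 1 library per genotype. AtCLB encodes a calcium-dependent lipid-binding protein with a C2 domain that is annotated as binding the promoter of the thalianol synthase gene THAS1 and as linked to drought and salt tolerance. FPKM were given for 33557 loci. In wild type 21074 loci lay above 0 and 16952 at 1 FPKM or more. In the library labelled mutant these were 21841 and 17216 loci. The steps of low values put the library labelled mutant at 1.21 times the depth of wild type, for which they imply roughly 14300000 to 15400000 mapped fragments. No replicate check of any difference was possible, and fold differences between groups of genes are on the log2(FPKM + 1) scale.

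The comparison asked which leaf transcripts differ in abundance when AtCLB is disrupted. In the library labelled mutant, dawn-phased clock genes, phosphate starvation genes, jasmonate genes, anthocyanin genes, senescence genes and salicylic acid defence genes were higher. Evening-phased clock genes, nuclear photosynthesis genes, cold-regulated genes and the plant defensin genes PDF1.2A, PDF1.2B and PDF1.2C were lower. The clock genes stood farthest apart, with a median difference of 3.92 for the dawn list and -4.60 for the evening list. Among 18171 loci at 1 FPKM or more in a library, 3124 (17.2%) were at least 2-fold higher and 1956 (10.8%) at least 2-fold lower in the library labelled mutant. Higher loci made up 61.5% of these. The share was 50.7% after the median ratio was set to 0, a shift of 0.21 on the log2 scale. It was 48.9% after a trend with transcript length and GC content was removed, which also set the median difference to 0.

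AtCLB itself (AT3G61050; TAIR10.1 chromosome 3, 22597216 to 22601412, plus strand) is a protein-coding gene with a transcript of 1969 nt and no overlapping annotated gene. Its value was 39.2 FPKM in wild type and 13.5 FPKM in the library labelled mutant, a log2 difference of -1.47. The transcript was 2.90-fold lower and remained at 34.5% of the wild type level. Of 909 loci of like expression, AtCLB itself included, 39 (4.29%, 95% Wilson interval 3.15 to 5.81%) had a difference as low. This value covers the whole locus, and the position of the insertion is not given in the sources used here, so the residual value does not settle whether intact transcript was made. The genotype is for this reason given as labelled.

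Reference genes lay close together. The 12 genes, among them ACT2, UBQ10, PP2AA3 and TIP41L, had a median difference of -0.03, and single genes ranged from -0.40 to 0.64. Across the alternatives, list means included, the value ran from -0.23 after the median ratio was set to 0 to 0.09 for the mean. None reached a 2-fold difference. UBQ10, a polyubiquitin gene, stood at 1012 FPKM in wild type and 1583 FPKM in the library labelled mutant, and ACT2, an actin gene, at 251 and 230 FPKM.

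Clock genes of opposite phase differed in opposite directions. All 5 dawn-phased genes were at least 2-fold higher in the library labelled mutant, and their median lay above all 10000 random lists. CCA1 and LHY, related MYB transcription factors at the core of the clock, stood at 7.39 and 3.41 FPKM in wild type and at 162 and 74.0 FPKM in the library labelled mutant. RVE1 stood at 1.62 and 38.8 FPKM, and RVE8 at 3.89 and 57.1 FPKM. Of 9 evening-phased genes 8 were at least 2-fold lower, and the median lay below all random lists. GRP7, a glycine-rich RNA-binding protein gene under clock control, was at 3794 FPKM in wild type and 30.3 FPKM in the library labelled mutant. ELF4 was at 343 and 4.95 FPKM, LUX at 56.6 and 1.05 FPKM, and FKF1, a blue-light receptor of the flowering pathway, at 78.9 and 0.526 FPKM. GI was the exception in the count, 1.82-fold lower at 34.0 FPKM in the library labelled mutant.

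**Figure D1:**
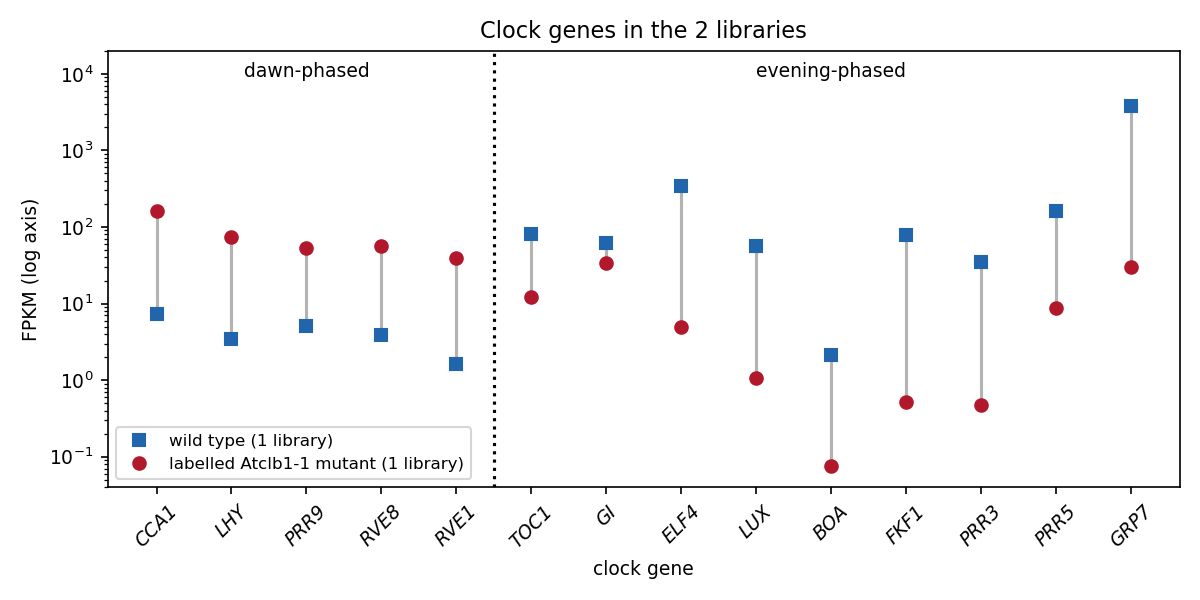
FPKM on a log axis of 5 dawn-phased and 9 evening-phased clock genes, with squares for the wild type library, circles for the library labelled Atclb1-1 mutant and a grey line joining the values of a gene. All dawn-phased genes are higher and all evening-phased genes lower in the library labelled mutant, from CCA1 at 7.39 against 162 FPKM to GRP7 at 3794 against 30.3 FPKM.

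All 8 phosphate starvation genes were at least 2-fold higher, with a median of 3.61 (2.22 with a pseudocount of 5) above all random lists. PHT1;4, a phosphate transporter gene, stood at 1.70 FPKM in wild type and 102 FPKM in the library labelled mutant, and SPX1, a phosphate sensor gene, at 18.5 and 264 FPKM. SPX3 was at 0.0786 FPKM in wild type and 45.3 FPKM in the library labelled mutant. IPS1, known as a noncoding RNA but annotated as protein-coding in TAIR10.1, was listed at 0 in wild type and stood at 18.6 FPKM. Among iron deficiency genes, 4 of 6 measured members were at least 2-fold higher, with a median of 1.06 at percentile 97.9. This list lay inside the middle 95% under 5 alternatives, with its lowest value, 0.62 at percentile 94.1, once the length and GC trend was removed. They were FRO3 (3.53 and 13.8 FPKM), OPT3 (43.3 and 93.6 FPKM), BTS (12.9 and 27.4 FPKM) and IMA2, which was listed at 0 in wild type and stood at 2.1 FPKM. The 3 measured ferritin genes had a median of -0.81 at percentile 7.40 and a mean of -0.33, with FER1 at 536 and 931 FPKM, FER3 at 166 and 84.4 FPKM and FER4 at 89.9 and 50.7 FPKM.

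Jasmonate genes were higher as a group. Of 17 measured members 16 were at least 2-fold higher and none lower, with a median of 2.26 above all random lists. VSP1 and VSP2, which encode vegetative storage proteins, stood at 2.41 and 21.7 FPKM in wild type and at 98.4 and 660 FPKM in the library labelled mutant. LOX3, a lipoxygenase gene of jasmonate synthesis, was at 9.29 and 229 FPKM, and JAZ10, a repressor of jasmonate signalling, at 1.04 and 39.3 FPKM. Genes that answer to ethylene and jasmonate together went mostly the other way, with 4 of 7 members at least 2-fold lower, 2 higher and a median of -1.81 at percentile 0.01. The median was -0.83 with a pseudocount of 5, and the mean of the members was -0.63 at percentile 3.54, inside the middle 95%. PDF1.2A was at 98.7 and 10.8 FPKM, PDF1.2C at 34.8 and 3.23 FPKM, and PDF1.2B at 6.39 and 0.447 FPKM. The basic chitinase gene CHIB was higher, at 0.614 and 21.6 FPKM.

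Of 22 salicylic acid defence genes 13 were at least 2-fold higher and 1 lower, with a median of 1.18 above all random lists. GRX480, a glutaredoxin gene, stood at 5.83 FPKM in wild type and 134 FPKM in the library labelled mutant, and WRKY18 at 16.5 and 171 FPKM. FMO1, a monooxygenase gene of systemic resistance, was at 0.449 and 16.2 FPKM, and WRKY38 at 1.32 and 25.8 FPKM. The marker PR1 was 1298 and 2756 FPKM, whereas PR5 was lower at 1382 and 516 FPKM. Both measured camalexin genes were higher, CYP71A13 at 1.49 and 12.2 FPKM and PAD3 at 12.2 and 31.7 FPKM. Rapid touch response genes had a median of 0.90 at percentile 99.8, with 5 of 12 at least 2-fold higher and 2 lower. The median was 0.59 once the length and GC trend was removed, and the mean of the members was 0.48 at percentile 90.3, inside the middle 95%. TCH4 was at 29.0 and 87.6 FPKM, ZAT12 at 112 and 325 FPKM, SZF1 at 67.5 and 174 FPKM, and ERF6 was lower at 25.9 and 7.61 FPKM.

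Of 16 measured flavonoid and anthocyanin genes 14 were at least 2-fold higher and 1 lower, with a median of 2.17 above all random lists. The MYB regulators PAP1 and PAP2 stood at 9.15 and 1.73 FPKM in wild type and at 134 and 20.6 FPKM in the library labelled mutant. DFR and LDOX, enzymes of the late anthocyanin pathway, were at 3.22 and 53.3 FPKM and at 1.26 and 24.2 FPKM. Senescence and dark-inducible genes had a median of 1.64 (1.08 with a pseudocount of 5) at percentile 99.99, with 7 of 12 at least 2-fold higher and 1 lower. SAG12, a cysteine protease gene used as a marker of leaf senescence, and DIN2 were listed at 0 in wild type and stood at 45.4 and 16.2 FPKM. SAG13 was at 122 and 1124 FPKM, and the transcription factor gene NAP at 8.46 and 82.9 FPKM.

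Nuclear photosynthesis genes were lower as a group, with 28 of 46 at least 2-fold lower, none 2-fold higher, and a median of -1.11 below all random lists. LHCB1.4 was at 2487 FPKM in wild type and 287 FPKM in the library labelled mutant, LHCB6 at 5253 and 1802 FPKM, and PSAN, a photosystem I subunit gene, at 4147 and 1452 FPKM. RBCS1B, a gene for the small subunit of Rubisco, was at 823 and 234 FPKM. RCA, the Rubisco activase gene, was 3643 and 6038 FPKM. Plastid-encoded loci, of which 74 of 133 were measured, had a median of 0.30 at percentile 86.2, with 15 at least 2-fold higher and 7 lower. The mean of these loci was 0.48 at percentile 99.2, outside the middle 95%, while the median was 0.14 after the median ratio was set to 0, 0.18 with a pseudocount of 5 and 0.00 with no filter. Their share of all FPKM was 6.25% in wild type and 4.34% in the library labelled mutant. In wild type 1 plastid locus, ATCG00010, had the highest value of that library, 30068 FPKM, so this share leans on single loci. The members farthest apart, ATCG00110, ATCG00080, ATCG00230 and ATCG00370, were each listed at 0 in 1 library.

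Drought and abscisic acid genes were split. Of 17 measured members 9 were at least 2-fold higher and 4 lower, with a median difference of 2.14-fold at percentile 99.98 (a log2 difference of 0.67 once the length and GC trend was removed). RD20, a caleosin gene, was at 74.3 FPKM in wild type and 1498 FPKM in the library labelled mutant, HB12 16.1-fold higher at 161 FPKM, HB7 at 9.05 and 97.9 FPKM, and the phosphatase gene HAI1 at 2.05 and 38.6 FPKM. RD29A, a dehydration-responsive gene, was lower at 784 and 88.0 FPKM. Cold-regulated genes were lower, with 6 of 11 at least 2-fold lower, 1 higher and a median of -1.36 at percentile 0.01. COR15B was at 2156 and 188 FPKM, COR413PM1 at 1141 and 218 FPKM, KIN2 at 4026 and 1087 FPKM, and KIN1 at 140 and 33.6 FPKM.

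**Figure D2:**
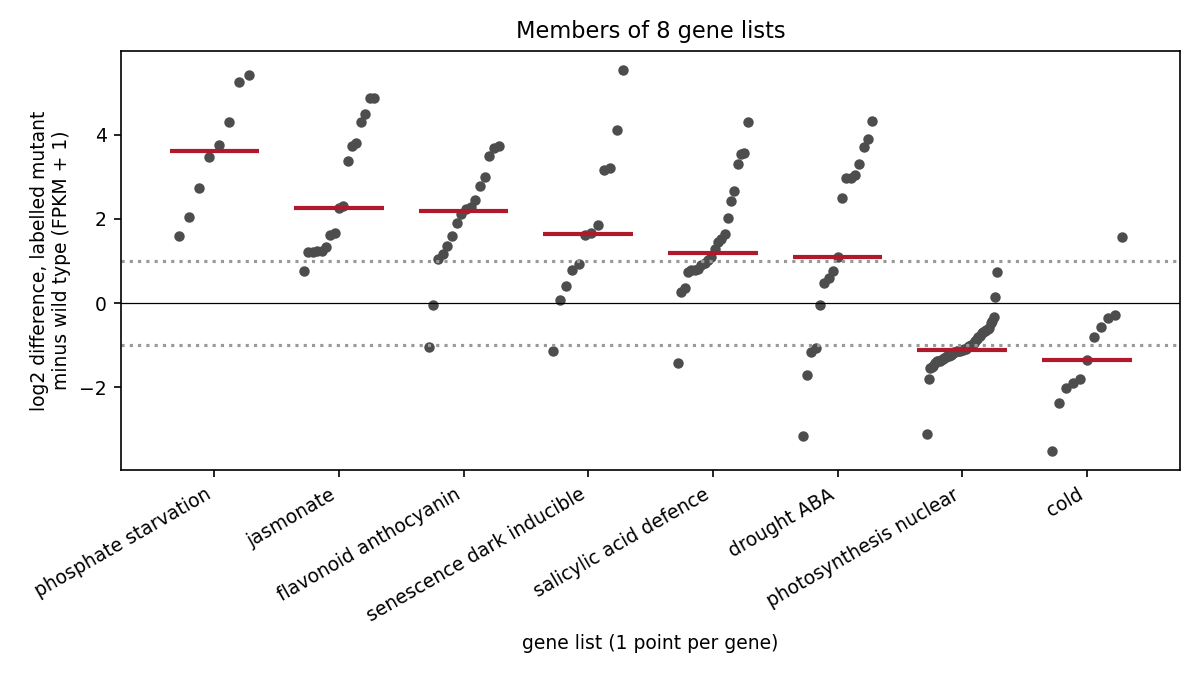
Log2 difference in FPKM + 1, library labelled mutant minus wild type, of each measured member of 8 gene lists, 1 point per gene, with a red bar at the list median and dotted lines at a 2-fold difference. The medians run from 3.61 for the phosphate starvation genes to -1.36 for the cold-regulated genes.

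The thalianol and marneral clusters, to which the annotated AtCLB target THAS1 belongs, were not measurable in these leaves, since all 8 members were listed at 0 in both libraries. Of 10 sterol and triterpenoid genes 2 were at least 2-fold higher and 2 lower, with a median of 0.04 that ran from -0.37 after trend removal to 0.23 for the mean across the alternatives. LAS1 was at 0.619 and 15.5 FPKM and SQE3 at 37.3 and 131 FPKM, while DWF1 was 3.12-fold lower than its wild type value of 37.3 FPKM and LUP1 was at 2.14 and 0.359 FPKM. The 9 measured relatives of AtCLB with C2 domains had a median of 0.22, at percentile 49.4, which ran from -0.23 after trend removal to 0.33 for the mean. NTMC2T6.2 (1.36 and 4.79 FPKM) and NTMC2T5.1 (3.88 and 10.5 FPKM) were at least 2-fold higher, and SYT1 stood at 131 and 105 FPKM. SYT4 was at 0.765 and 1.2 FPKM.

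**Figure D3:**
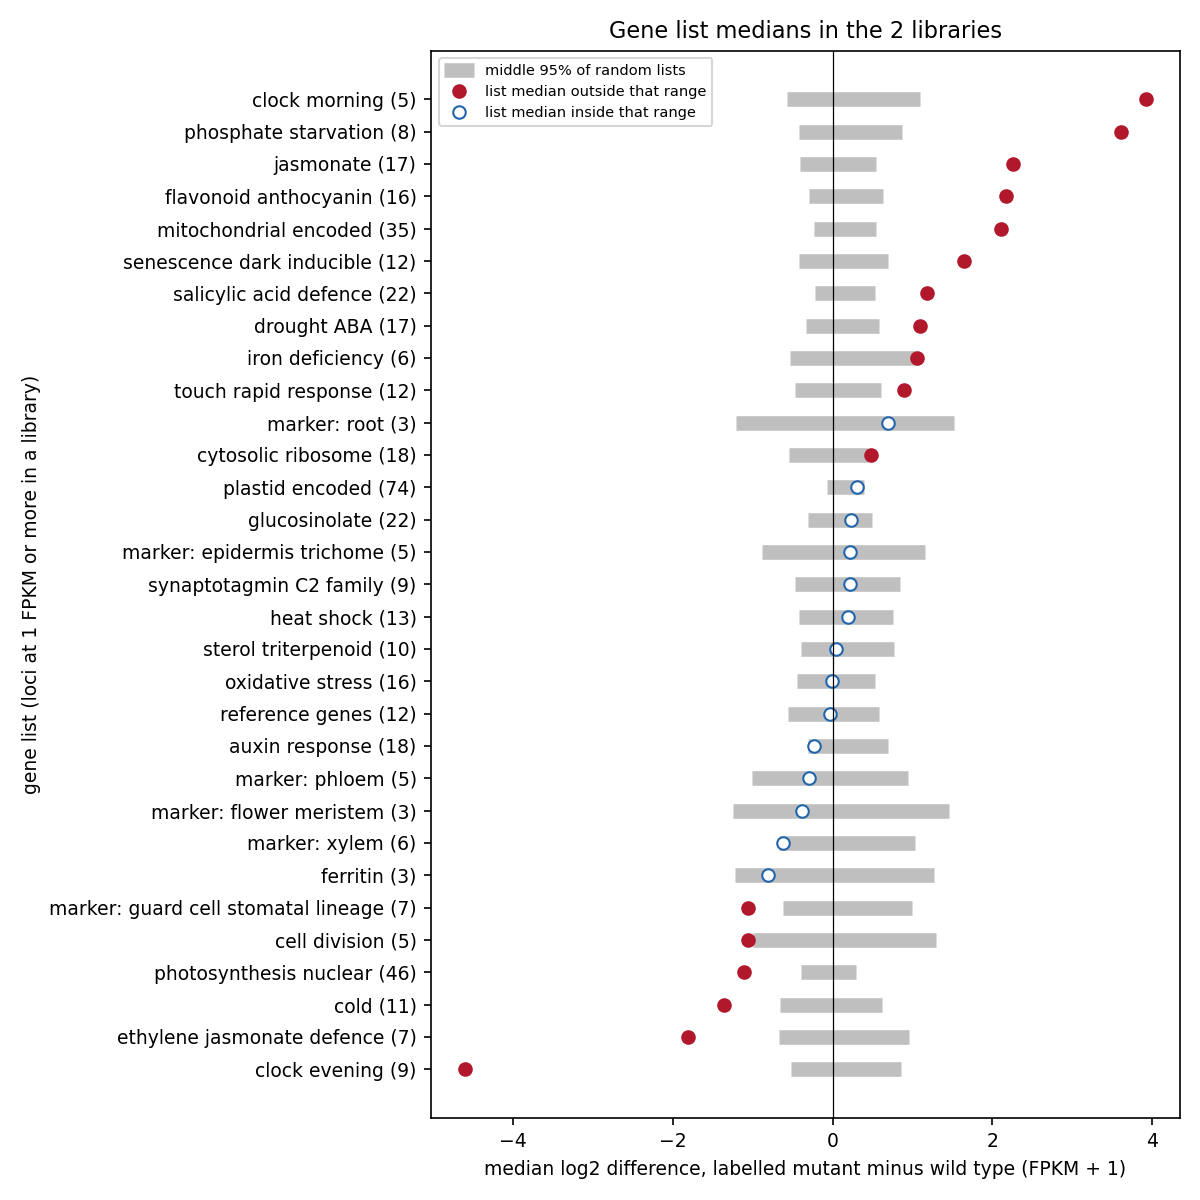
Median log2 difference in FPKM + 1, library labelled mutant minus wild type, of each placed gene list (points, with the number of measured loci), over the middle 95% of 10000 random lists matched on expression (grey bars). Of 31 lists 17 lie outside their range, 11 above and 6 below; medians of the sterol, oxidative stress, reference, C2, heat shock, glucosinolate, auxin and epidermis lists change sign under another scaling or filter or once the length trend is removed.

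The glucosinolate, oxidative stress, heat shock and cytosolic ribosome lists had median differences of less than 2-fold. Glucosinolate genes had a median of 0.23 at percentile 69.6, from -0.03 after trend removal to 0.33 with the same nuclear total, with 3 of 22 at least 2-fold higher and 2 lower. The myrosinase genes TGG1 and TGG2 were the lower members, at 1017 and 88.1 FPKM and at 738 and 156 FPKM, while MYB34 was at 4.71 and 18.7 FPKM and CYP79B3 at 21.9 and 53.9 FPKM. Oxidative stress genes had a median of -0.00, from -0.21 after the median ratio was set to 0 to 0.28 for the mean across the alternatives, with 4 of 16 at least 2-fold higher and 2 lower. CAT2, a catalase gene, was at 282 and 1930 FPKM, GSTF7 at 64.1 and 413 FPKM, OXI1 at 0.662 and 2.91 FPKM, and CSD2, a superoxide dismutase gene, at 94.6 and 34.2 FPKM. Heat shock genes had a median of 0.19 at percentile 48.6, from -0.15 after trend removal to 0.28 with the same nuclear total, with 3 of 13 higher and 2 lower. GOLS1 was at 7.54 and 69.4 FPKM, HSP90.1 at 1.82 and 18.4 FPKM, HSP70 at 1.79 and 10.9 FPKM, and HSP17.6B at 5.80 and 0.533 FPKM. Cytosolic ribosomal protein genes had a median of 0.48 at percentile 98.1, with none of 18 reaching 2-fold. The median was 0.27 after the median ratio was set to 0, and 0.32 at percentile 97.0, inside the middle 95%, after trend removal. RPL4A was at 91.3 and 144 FPKM.

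Auxin response genes had a median of -0.23 at percentile 4.08, with 4 of 18 at least 2-fold higher and 4 lower. Across the alternatives it ran from -0.35 after the median ratio was set to 0 to 0.71 among the 10 members at 5 FPKM or more in a library, and with no filter it was -0.21 at percentile 1.97, outside the middle 95%. The growth-linked genes SAUR24 (20.4 and 3.16 FPKM) and SAUR23 (4.84 and 0.647 FPKM) were lower, while GH3.5 (0.994 and 7.10 FPKM) and GH3.3 (1.66 and 7.79 FPKM), which conjugate auxin, were higher. Of 5 measured cell division genes 3 were at least 2-fold lower, with a median of -1.06 at percentile 1.74. The median was -0.42 with a pseudocount of 5, -0.62 with no filter and -1.63 with a pseudocount of 0.1, the last at percentile 3.08, inside the middle 95%, and no member reached 5 FPKM. CDKB2;1 was at 2.32 and 0.458 FPKM, KNOLLE at 3.45 and 1.05 FPKM, MCM2 at 4.1 and 1.44 FPKM, and CYCB1;2 at 1.29 and 0.161 FPKM.

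Among markers of cell types, those of the stomatal lineage were mostly lower. Of 7 measured guard cell and stomatal genes 4 were at least 2-fold lower and 1 higher, with a median of -1.05 at percentile 0.28 (-0.34 with a pseudocount of 5 and -0.48 with no filter). EPF1, a peptide gene of stomatal patterning, was at 6.76 and 0.340 FPKM, GC1 at 144 and 31.8 FPKM and MYB60 at 18.0 and 7.71 FPKM, while the potassium channel gene KAT1 was at 12.8 and 32.4 FPKM. Xylem genes had a median of -0.62 at percentile 3.08, and lay outside the middle 95% under 4 of 9 alternatives. Their values ran from -0.34 with a pseudocount of 5, inside that range, to -1.12 over the 3 members at 5 FPKM or more. The most different were LAC4 at 7.22 and 2.60 FPKM and XCP2 at 24.0 and 10.5 FPKM. Phloem genes had a median of -0.29 at percentile 22.0, from -0.56 after trend removal to -0.10 for the mean, with SWEET12 at 115 and 73.0 FPKM. Epidermis and trichome genes had a median of 0.22 and a mean of -0.04, and the alternatives ran from -0.77 over the 3 members at 5 FPKM or more to 0.36 with a pseudocount of 0.1, with ATML1 at 8.70 and 3.64 FPKM. The 3 measured root markers had a median of 0.69 at percentile 76.4 (0.12 at percentile 97.9 over all 9 with no filter) and the 3 flower markers one of -0.39 at percentile 31.3. The flower value ran from -0.69 with a pseudocount of 0.1 to 0.00 over all 9 members with no filter. None of the 8 seed markers reached 1 FPKM.

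Mitochondrial-encoded loci were higher beside these groups. Of 35 measured loci 29 were at least 2-fold higher and none lower, with a median of 2.11 above all random lists. The median was 3.61 with a pseudocount of 0.1 and 0.82 with a pseudocount of 5, and with no filter it was 0.00 at percentile 50 over all 146 loci, 111 of which lay under 1 FPKM in both libraries. Their share of all FPKM was 0.0246% in wild type and 0.145% in the library labelled mutant. How mRNA was selected is not given in the sources used here, so this difference cannot be assigned to genotype. ATMG01370 was at 0.344 and 49.9 FPKM, ATMG00110 at 0.129 and 20.2 FPKM, and ATMG01220 at 0.332 and 13.0 FPKM. ATMG00150 was listed at 0 in wild type and stood at 9.23 FPKM. Across nuclear loci at 1 FPKM or more in both libraries the median difference was 0.01 in the decile of loci with the shortest transcripts (79 to 919 nt), -0.02 and 0.04 in the next deciles, and higher in each longer decile up to 0.50 in the longest (3169 to 15700 nt).

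Among single loci, NIT2, a nitrilase gene, was 302-fold higher (1.17 and 355 FPKM). NATA1, an acetyltransferase gene, was 100.1-fold higher (5.24 and 525 FPKM). SRG3, a glycerophosphodiester phosphodiesterase gene, was at 0.898 and 173 FPKM, and the pseudogene AT2G04460 at 0.228 and 148 FPKM. AT3G25011 was listed at 0 in wild type and stood at 180 FPKM in the library labelled mutant. Its TAIR10.1 transcript has 558 nt, but the length the authors used is not known, so few reads may lie behind this value. The lowest differences outside the clock lists included GER3, a germin-like protein gene (327 and 0.135 FPKM), the pseudogene AT1G69140 (286 and 0.261 FPKM) and AT1G07050 (234 and 0.292 FPKM). COR27, a cold-regulated gene under clock control, was at 173 and 0.343 FPKM, and AT4G33980 at 130 and 0.742 FPKM. The clock lists do not hold all clock-controlled genes, so these low values need not be separate from the difference in clock genes. Of the 24 loci with the highest or lowest differences, 13 had transcripts under 500 nt or no annotated length, among them U60.1F, AT5G58595, MIR156d, MIR167b, MIR168a and AT5G66607, each listed at 0 in 1 library. In all, 47 loci were listed at 0 in 1 library and stood at 10 FPKM or more in the other. Of these 15 were annotated as protein-coding, IPS1 included, with transcripts of 500 nt or more. These lengths are from TAIR10.1 and can differ from those behind the FPKM. RTFL13 (712 nt) and AT1G14642 (132 nt) both stood at 14.1557 FPKM in the library labelled mutant. Some of the 15 may therefore also rest on few reads.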

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

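The correction for transcript length and GC content and the restriction to protein-coding loci of 500 nt or more were chosen only after the result was seen. With a pseudocount of 5 the counts of loci at least 2-fold higher and lower were 1774 and 1058, and with a 4-fold threshold they were 961 and 480, as fewer loci pass either by construction. The other alternatives kept both counts within 1.5-fold of the main values, from 2366 to 3774 higher and from 1518 to 2472 lower. Setting the median ratio to 0 kept 2499 of the higher and 1956 of the lower loci. Because this step lowers every mutant value, all lower loci stay lower and no new locus becomes higher by construction. Removing the trend kept 2328 and 1901. The AtCLB difference ran from -1.25 to -1.66. Of 31 list medians in 273 alternative values, 229 moved by less than the spread (SD) of matched random lists and 44 moved further; no median of at least 2-fold changed sign, while those of 8 lists nearer 0 did under at least 1 alternative, as given beside them. Of 739 alternative values for named genes, 564 stayed within the spread of the reference genes and 175 moved further, and no difference of at least 2-fold changed sign. For a single gene a pseudocount cannot change the sign, and the rescalings shift values by far less than 2-fold. Only trend removal could therefore have changed the sign of such a difference. Between 15 and 18 lists lay outside the middle 95% against 17 in the main analysis. No paired analysis was possible because each genotype had 1 library. The authors' own calls were not run, since no test values were analysed here. The number of reads behind each gene is not known, which limits the low genes.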

Other observations

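The tests of harvest time, of growth state and of reads from an overlapping gene were chosen only after the result was seen, as were the length and GC correction, the chromosome windows and the annotated families below. Families were taken from the annotation's product names, and 163 had at least 10 measured members. Of these 16 lay above the middle 95% of matched random lists and 25 below it. If families were random draws of loci, 4.08 would be expected on each side. Members of a family need not vary independently, so the excess is a description and not a test. In the library labelled mutant, 13 of 17 berberine bridge enzyme-like genes were at least 2-fold higher and none lower, and the median lay above all random lists. AT2G34810 reached 513 FPKM in that library against 11 FPKM in wild type. The peroxidase superfamily had 12 of 20 members higher and 2 lower, with a median of 1.34. PRX52 was at 1.29 and 28.6 FPKM, while PRXR1 was lower at 1667 and 318 FPKM. The GH3 family, which joins amino acids to hormones, had 7 of 10 members higher, with DFL1 at 3.66 and 50.2 FPKM and PBS3, a gene of salicylic acid synthesis, at 15 and 85.1 FPKM. Resistance genes of the TIR-NBS-LRR class had 24 of 40 members higher, none lower and a median of 1.13, which was 0.57 once the length and GC trend was removed. Pectin lyase-like genes went the other way, with 18 of 41 lower and 6 higher and a median of -0.78, and AT5G63180 was at 120 and 5.13 FPKM. FKBP-like peptidyl-prolyl isomerases had 9 of 13 members lower and 1 higher, with a median of -1.27.

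Among stretches of 20 neighbouring measured loci, median differences ran from -0.70, on chromosome 5 from 26207654 to 26308237, to 1.42. The highest stretch lay on chromosome 1 from 19158746 to 19299169 (TAIR10.1). It held a cluster of leucine-rich repeat receptor kinase genes, with IOS1 at 2.92 and 25.6 FPKM and AT1G51860 at 1.34 and 41.7 FPKM, beside the auxin amidohydrolase genes IAR3 (25.3 and 139 FPKM) and ILL5 (0.130 and 23.5 FPKM). AT1G51805 in the kinase cluster was at 61.8 and 68.9 FPKM, and LYK3 in the same stretch was lower, at 25.5 and 1.61 FPKM. The product family named leucine-rich repeat protein kinase had 77 measured members, 13 at least 2-fold higher and 16 lower. Its median was -0.14 at percentile 0.21. Next to AtCLB on chromosome 3, PP2-A13, which overlaps another annotated gene, was 8.35-fold higher (12.8 and 106 FPKM). AT3G61028, 4 genes away on the other side, stood at 0.0727 and 8.54 FPKM. Under the naming rule applied to protein-coding loci of 500 nt or more, the 12 highest also held the methyltransferase gene BSMT1 (0.516 and 102 FPKM), the phosphatase genes PS2 (3.64 and 221 FPKM) and PEPC1 (0.397 and 72.8 FPKM), and OSM34, listed at 0 in wild type and at 54.1 FPKM in the library labelled mutant.

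Dawn-phased clock genes were higher and evening-phased ones lower in the library labelled mutant. A trend with transcript length or GC content does not account for this, because the evening list kept a median of -4.89 after its removal. Harvest at different times of day stays open, and the gap of 8.52 between the medians of both lists restates the pattern and does not test it. Harvest time and genotype cannot be told apart, since each genotype has 1 library and harvest times are not given in the sources used here. An effect of AtCLB on the clock stays open in the same way and was not tested.

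Phosphate, jasmonate, anthocyanin and senescence genes were higher together. The lowest of their 4 medians was 1.35 after the length and GC trend was removed and 1.46 after the median ratio was set to 0, which argues against that trend and against a shift in FPKM scaling as the whole cause. Another growth state or environment of the plants stays open, and the phosphate list's median of 3.61 is part of the pattern and does not test it. Harvest at different times of day was not tested for these or the other gene lists and stays open for them too. Growth state, harvest time and genotype cannot be told apart with 1 library each, and an effect of AtCLB itself was not tested separately.

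AtCLB transcript remained at 34.5% of the wild type level in the library labelled mutant. Reads of an overlapping gene are excluded as far as the annotation goes, with 0 overlapping loci. RNA of the sequenced wild type sample mixed into that library is argued against by 81 of 2786 loci at 50 FPKM or more in wild type that lay under 10% of that level. Whether the lower value exceeds the ordinary spread between these libraries stays open. Of loci of like expression, AtCLB itself included, 4.29% were as low, and the interval of 3.15 to 5.81% spans 5%. That share cannot decide it, since these loci come from the same libraries and carry any difference of genotype, harvest or growth. The interval also treats loci as independent. A partial transcript on either side of the insertion is a further possibility that locus-level values could not test.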
